A study of Mus musculus with 15 samples.

How the data were processed

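Total RNA of SCN punches was sequenced from C57BL/6 mice aged 8 to 12 weeks, collected at CT 4 or 16, with 2 to 4 punches pooled per library, per the labels. Libraries were made with a TruSeq kit and sequenced on an Illumina HiSeq instrument, per the design text. The authors deposited a table of read counts, whole numbers per gene and library that were not normalized. The submitters' processing notes name STAR, featureCounts, DESeq2 and the mouse build mm10. Versions, annotation, strand setting and read filters are not given in the sources used here. The table also holds each gene's exonic length in bases, per the file headers, which was used only to look for trends with length. The table lists 24419 genes, of which 3619 had no count in any library and 54 had exons on more than one chromosome. It holds 0 genes of the mitochondrial chromosome, so the list of mitochondrially encoded messages has no members here. Each library was matched to its group and replicate number by its label. Nothing in the labels says which mice were pooled, so p-values measure the spread between pools.

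Total counts ran from 32580803 to 68757624 per library. Within groups, log2 CPM of library pairs correlated at 0.9803 to 0.9899, and chi-square per degree of freedom lay between 6.765 and 129.3, so that no pair was alike within sampling noise and each library counted as 1 replicate.

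Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr on the 4 groups, which left 16910. TMM factors were computed, 1 model with 4 group means was fitted to the 15 libraries with 11 residual degrees of freedom, and 5 contrasts were tested with the robust quasi-likelihood test. These were DKO against control at CT4 and at CT16, CT16 against CT4 in control and in DKO, and the interaction. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Standard errors are the absolute log2 fold change divided by the square root of the F statistic. CPM used TMM-scaled library sizes, and log2 CPM a prior count of 2. Per comparison, the genes named were Nr1d1 and Nr1d2, all tested genes of the clock lists, and the 8 largest rises and 8 largest falls among called genes with a mean log2 CPM of at least 1 and no overlap between groups. For the interaction the 10 smallest p-values were taken. Up to 4 members of smallest p were named from each other list with a called member or past its test. Thra, drawn in the plot of CPM per library, and its chromosomal neighbours were chosen after their values were seen. Some genes that meet these rules are not reported here.

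Fixed with these rules were 34 lists with 483 genes, of which 467 were in the table and 453 tested, covering clock genes, SCN function, cell types and neighbouring regions a punch could hold, stress and metabolism. The 31 lists with at least 5 tested members were tested with camera of limma 3.58.1 at its preset inter-gene correlation of 0.01. Camera was also run with an estimated correlation, under which only the clock lists at CT16 and the glucocorticoid-responsive genes in both time comparisons passed. Members were also adjusted over the list alone. Designs, lists, naming rules and the first set of other settings below were chosen before the data were examined.

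These other settings were RLE and upper quartile factors, DESeq2 1.42.0, limma voom with quality weights, no filter and a stricter filter on low counts, a fit on the compared groups alone, the replicate number as a block, a myelin score as covariate, removal of mitochondrial and haemoglobin genes, an estimated correlation, and each library left out in turn. Added after the data were seen were myelin and neighbouring nuclei scores as covariates, 2 surrogate variables from sva 3.50.0, and the exclusion of 3 libraries (DKO CT16 replicates 3 and 4 and control CT4 replicate 1). For a named gene, direction was compared between settings only where it was called in either. Removal of mitochondrial and haemoglobin genes left the same 16910 tested genes, so it could not change a call, though it counts among the alternatives below.

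The steps were tested on simulated counts with 200 changed genes, drawn from genes with a mean of at least 2 CPM. A separate list of 20 such genes was raised by a log2 change of 0.5. The recovery given here thus does not cover genes of lower expression. At a log2 change of 0.5, 1 and 2, respectively, 32 of 67, 63 of 67 and 63 of 66 changed genes were recovered for the CT4 comparison (16741 genes). For CT16 (16727 genes) these were 51, 62 and 66, for time in control (16753 genes) 42, 61 and 65, and for time in DKO (16714 genes) 41, 61 and 66. False calls were 4.57%, 2.49%, 2.13% and 4.21% of all calls. Each gene was drawn separately around 1 mean for all libraries, apart from the changes put in. The simulated counts thus hold no tissue differences between libraries and no correlation between genes, and these rates do not cover such structure in the real counts. Figures were drawn with matplotlib 3.10.9.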

Results

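Gene expression was measured by RNA sequencing in tissue punches of the suprachiasmatic nuclei (SCN), the paired hypothalamic nuclei that hold the central circadian pacemaker of mammals. The mice lacked both REV-ERB alpha and REV-ERB beta (double knockout, DKO) or were controls. These nuclear receptors, encoded by Nr1d1 and Nr1d2, repress transcription and are part of the molecular clock. Punches were taken at circadian time (CT) 4 or 16 h, which lie in the subjective day and the subjective night, and 2 to 4 punches were pooled for each library. The 15 libraries were 3 control and 3 DKO libraries at CT4 and 5 control and 4 DKO libraries at CT16. The total count per library ran from 32580803 in control CT16 replicate 1 to 68757624 in DKO CT16 replicate 3. The 10 most abundant genes took between 3.17% and 4.41% of a library's counts. All 4 comparisons between groups and the interaction below were tested over 16910 genes, and values are log2 fold changes ± standard error from the fitted model unless another unit is given. The largest rises and falls are those among called genes with a mean log2 CPM of at least 1 and no overlap between the libraries compared.

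The counts of the targeted genes themselves did not fall in DKO. Nr1d1 lies on chromosome 11 (98767932 to 98775377, minus strand, mm10) and Nr1d2 on chromosome 14 (18204056 to 18239106, minus strand). At CT4, expression of Nr1d1 in CPM, counts scaled to the size of the library, stood at 226 to 252 in the DKO libraries and 198 to 282 CPM in the control libraries, a difference of -0.02 ± 0.14. At CT16 it stood at 241 to 378 CPM in the 4 DKO libraries and 135 to 150 CPM in the 5 control libraries, and Nr1d1 rose by 1.15 ± 0.12 (edgeR quasi-likelihood test, adjusted p = 6.93e-05). Nr1d2 rose by 0.47 ± 0.09 at CT4 (adjusted p = 0.0212) and by 1.07 ± 0.07 at CT16 (adjusted p = 2.79e-07). The deposited counts sum all exons of a gene, so transcripts that lack only some exons still count, and these values do not check the genotype labels.

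The comparison of DKO with control at CT4 set the genotypes against each other in the subjective day. Clock transcripts were among those that rose in DKO. Nfil3, a repressor of D-box genes, rose by 1.35 ± 0.16 (edgeR quasi-likelihood test, adjusted p = 0.00156), and Npas2, a partner of BMAL1, by 1.20 ± 0.17 (adjusted p = 0.00666). The cryptochrome genes Cry1 and Cry2 rose by 0.70 ± 0.14 and 0.43 ± 0.06. Dbp, Bhlhe40 and Per3 rose by 0.89 ± 0.18, 0.50 ± 0.10 and 0.42 ± 0.09. Of 19 alternatives, the call of Dbp was lost in 8 and those of Cry1, Bhlhe40 and Per3 in 7 each. That of Npas2 was lost in 1, while those of Nfil3 and Cry2 were kept in all. Outside the clock, large rises included those of the secreted matrix protein gene Spon2 (3.02 ± 0.56), Cplx3 (2.35 ± 0.50) and Plvap (2.29 ± 0.26), a gene of the diaphragms of fenestrated endothelium. Spon2 was low and uneven in control, at 0.65 ± 0.62 CPM (SD, n = 3). Its call was lost in 8 of 19 alternatives and that of Cplx3 in 7, while that of Plvap was kept in all. The largest falls were those of the immediate early gene Nr4a3 (-1.45 ± 0.29), Pmaip1 (-1.34 ± 0.29), Ciita (-0.97 ± 0.21) and Mfge8 (-0.92 ± 0.08), which encodes a secreted phagocytosis bridge made by glia. The call of Nr4a3 was lost in 9 of 19 alternatives and those of Pmaip1 and Ciita in 8 each, while that of Mfge8 was kept in all.

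In all, 217 of the 16910 genes passed an adjusted p of 0.05 at CT4 (edgeR quasi-likelihood test, Benjamini-Hochberg), 97 higher and 120 lower in DKO. Of these, 23 rose and 9 fell by more than 2-fold. Among all genes, 25.4% had no overlap between the 3 DKO and 3 control libraries, where chance gives 10%. Car14 (1.72 ± 0.37), C2cd4b (1.66 ± 0.26), Crispld2 (1.46 ± 0.27) and Cdkn1a (1.40 ± 0.16) were also among the 8 largest rises, and Exoc3l4, Syt17 and Col9a3 among the 8 largest falls, at -0.89 to -0.78. Fabp7, a fatty acid binding protein of astrocytes and neural progenitors, rose by 1.30 ± 0.18.

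Of 12 measured clock repressors and E-box outputs, 4 rose at CT4, none fell and 8 did not pass; adjusted over the list alone, 8 rose. The list moved up against the other genes (camera, adjusted p = 2.97e-10, adjusted p = 0.147 with an estimated correlation). Per1 (-0.04 ± 0.13) and Per2 (0.06 ± 0.23) did not pass. Of 9 clock genes with ROR/REV-ERB elements, Npas2, Nfil3 and Cry1 rose and 6 did not pass; adjusted over the list alone, 4 rose and 2 fell. That list also moved up (camera, adjusted p = 3.35e-05, adjusted p = 0.147 with an estimated correlation). Arntl, which encodes BMAL1, stood at 0.65 ± 0.16 (adjusted p = 0.0661).

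Of 17 glucocorticoid-responsive genes, 3 rose at CT4 and 14 did not pass (4 rose adjusted over the list alone, camera, adjusted p = 1.13e-07, adjusted p = 0.254 with an estimated correlation). They were Cdkn1a, Tsc22d3 (0.72 ± 0.08) and Klf9 (0.51 ± 0.11). Of 28 cytosolic ribosomal protein genes, Rps24 (0.33 ± 0.05) and Rpl4 (0.19 ± 0.04) rose and 26 did not pass (6 rose adjusted over the list alone, camera, adjusted p = 1.13e-06, adjusted p = 0.332 with an estimated correlation). The calls of Rpl4 and Car14 were each lost in 10 of 19 alternatives. Genes called higher at CT4 had a median exonic length of 2192 bases and those called lower 4422, against 2808.5 among tested genes. Among temperature-responsive genes the cold-inducible Rbm3 rose by 0.59 ± 0.09, and among ion channels of SCN firing Cacna1d fell by 0.46 ± 0.10; neither list passed its test. The lists of reactive glia and complement (median 0.28, camera, adjusted p = 0.0132, adjusted p = 0.558 with an estimated correlation) and of nuclear RNAs (median -0.20, camera, adjusted p = 0.0261, adjusted p = 0.481 with an estimated correlation) passed with no member called over all genes. Adjusted over the list alone, 1 gene of the former rose, and 2 of the latter fell.

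Tissue markers differed between the CT4 groups as well. SCN identity factors and markers were lower in DKO (median -0.70 over 16 genes, none called over all genes; adjusted over the list alone, 7 fell and 1 rose, camera, adjusted p = 0.000113, adjusted p = 0.502 with an estimated correlation). Lhx1 stood at -1.47 ± 0.48 (adjusted p = 0.182) and Zfhx3 at -0.74 ± 0.23 (adjusted p = 0.162). Markers of neighbouring hypothalamic nuclei were higher (median 0.57 over 23 genes, none called either way, nor adjusted over the list alone, camera, adjusted p = 0.00164, adjusted p = 0.481 with an estimated correlation), with Pmch at 4.46 ± 2.16 (adjusted p = 0.372). Pmch was very uneven between the DKO CT4 libraries, with a mean of 36.4 CPM and an SD of 51.1 CPM. Markers of ependyma and tanycytes were higher too (median 0.54 over 12 genes, none called, nor adjusted over the list alone, camera, adjusted p = 0.00323, adjusted p = 0.558 with an estimated correlation). Receptors of SCN neuropeptides and light input had a median of 0.02 but a mean of -0.38, and the list test gave the lower direction (camera, adjusted p = 0.0436, adjusted p = 0.3 with an estimated correlation). None of its 15 genes was called over all genes and 6 fell adjusted over the list alone; Grpr stood at -1.01 ± 0.26 (adjusted p = 0.0645). Control CT4 replicate 1 had a neighbouring nuclei score of 0.576, near the 0.521 to 0.833 of the DKO CT4 libraries, while the other control CT4 libraries stood at -0.732 and -0.37. Leaving out that library alone gave 190 called genes at CT4, 130 of them among the 217, and leaving out control CT4 replicate 3 gave 16. Without that library and DKO CT16 replicates 3 and 4, which also stand apart in tissue markers (a choice made after the data were seen), 606 genes were called, 192 of them among the 217.

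The comparison at CT16 asked the same in the subjective night, and clock transcripts again rose in DKO. Npas2 rose by 1.92 ± 0.14 (3.79-fold, adjusted p = 3.07e-06), Dbp, a D-box activator, by 1.90 ± 0.15 (3.73-fold), Ciart, a repressor of CLOCK and BMAL1, by 1.49 ± 0.13, Nfil3 by 1.37 ± 0.13 and Arntl by 1.18 ± 0.13 (2.27-fold). Npas2 stood at 66.3 ± 14.2 CPM (SD, n = 4) in DKO and 17.5 ± 1.84 CPM (SD, n = 5) in control. Large rises included those of Spon2 (5.55 ± 0.55), Fabp7 (3.76 ± 0.16) and Plvap (2.97 ± 0.21). Fabp7 (chromosome 10, 57784923 to 57788450, mm10) was 13.6-fold higher, and Spon2 lies on chromosome 5 (33213518 to 33218238). The largest falls were those of Kirrel2 (-2.21 ± 0.28), a cell adhesion gene of the nephrin family, Smyd1 (-1.20 ± 0.26), Slc25a34 (-1.16 ± 0.19) and Mfge8 (-1.12 ± 0.07).

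At CT16, 788 genes passed, 478 higher and 310 lower in DKO, of which 91 rose and 19 fell by more than 2-fold. No overlap between the 4 DKO and 5 control libraries was seen in 6.97% of genes, where chance gives 1.59%. Car14 (2.79 ± 0.31), Cplx3 (2.73 ± 0.38), Crispld2 (2.59 ± 0.23) and Aldh1a2 (2.40 ± 0.34), an enzyme of retinoic acid synthesis, also rose. Atp8b5 (-1.09 ± 0.25), the serotonin receptor gene Htr3a, the fatty acid elongase gene Elovl2 (-0.99 ± 0.13) and Slc2a4 (-0.97 ± 0.24), which encodes the insulin-responsive glucose transporter GLUT4, also fell.

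**Figure D1:**
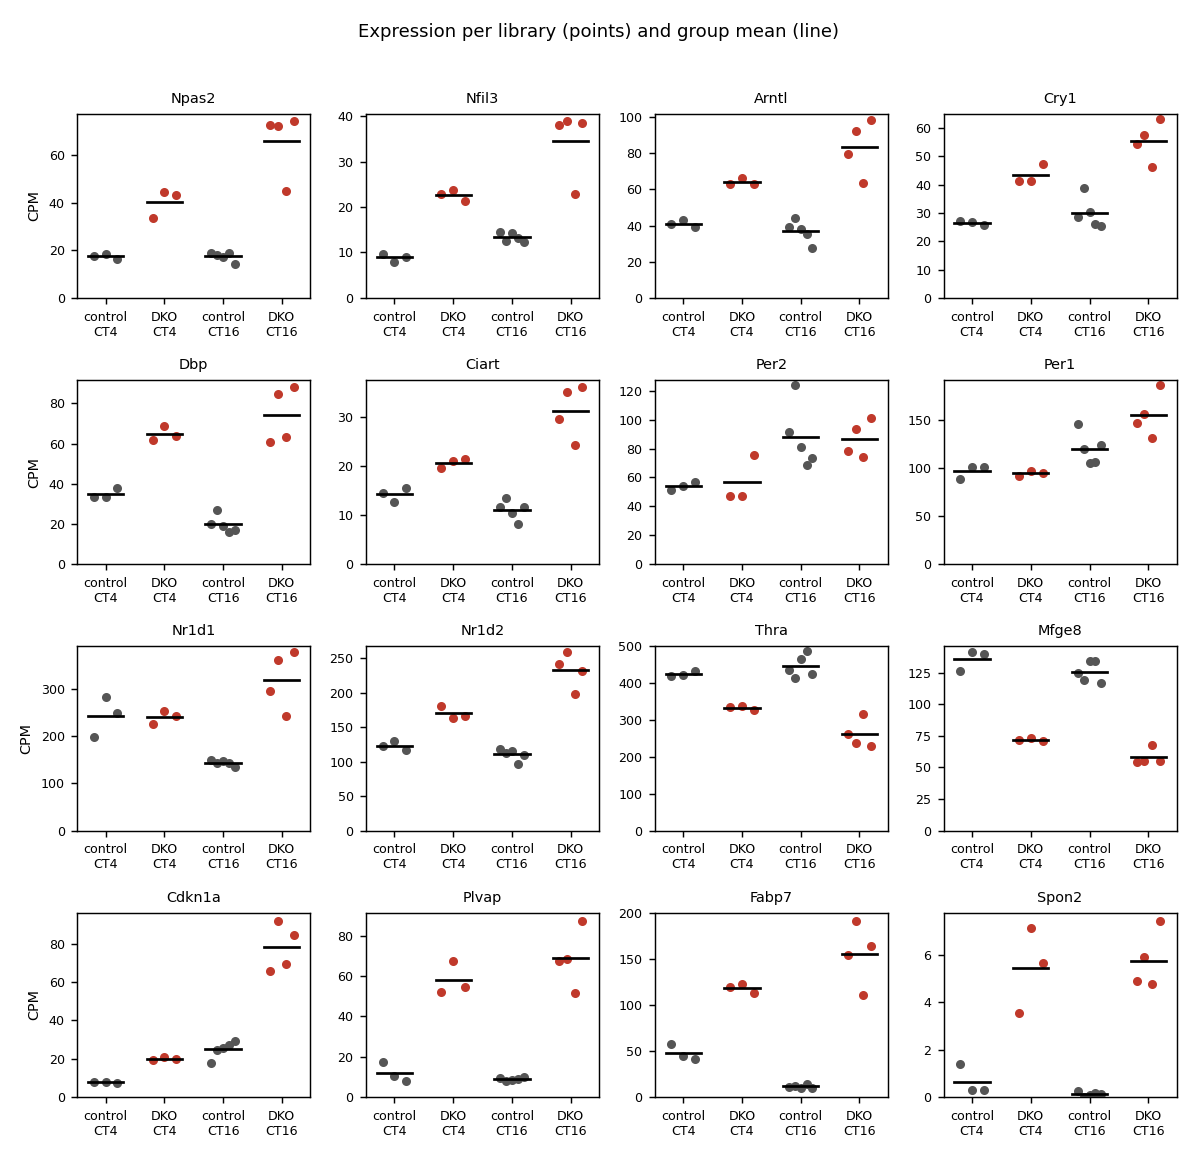
CPM in each library (points; black lines are group means) for 16 genes, by genotype and circadian time; axes start at 0. Npas2 lies between 45.0 and 74.7 CPM in the DKO CT16 libraries and between 14.4 and 18.9 CPM in the control CT16 libraries, while the ranges of Per2 overlap.

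Of the 12 clock repressors and E-box outputs, 8 rose at CT16 and 4 did not pass (10 rose adjusted over the list alone, camera, adjusted p = 2.24e-33, adjusted p = 0.00251 with an estimated correlation). Besides Dbp and Ciart these were Hlf (0.96 ± 0.12), Bhlhe41 (0.94 ± 0.10), Bhlhe40 (0.66 ± 0.08), Per3 (0.59 ± 0.07), Cry2 (0.55 ± 0.05) and Tef (0.35 ± 0.06). Per2 stood at -0.01 ± 0.18, and Per1 at 0.37 ± 0.10 (adjusted p = 0.0565). Of the 9 clock genes with ROR/REV-ERB elements, 5 rose and 4 did not pass (5 rose adjusted over the list alone, camera, adjusted p = 1.95e-15, adjusted p = 0.00251 with an estimated correlation). Cry1 rose by 0.89 ± 0.11 and Clock by 0.22 ± 0.06 (lost in 11 of 22 alternatives), while Rora (0.25 ± 0.25) and Rorb (-0.02 ± 0.22) did not pass.

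Of 19 temperature-responsive genes, 9 fell in DKO at CT16 and 10 did not pass; adjusted over the list alone, 10 fell and 2 rose (camera, adjusted p = 3.06e-06, adjusted p = 0.265 with an estimated correlation). The heat shock genes Hspa1b (-0.91 ± 0.18) and Hspa1a (-0.78 ± 0.16) fell with the co-chaperone gene Stip1 (-0.36 ± 0.05) and the endoplasmic reticulum chaperone gene Hspa5 (-0.33 ± 0.07). Hspa1a and Hspa1b are near-identical copies, so the division of counts between them is uncertain. Of the 17 glucocorticoid-responsive genes, 6 rose and 11 did not pass (9 rose adjusted over the list alone, camera, adjusted p = 1.04e-11, adjusted p = 0.0941 with an estimated correlation), with Cdkn1a at 1.65 ± 0.12, Mt2 at 0.82 ± 0.12, Htra1 at 0.53 ± 0.08 and Tsc22d3 at 0.48 ± 0.07.

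Astrocyte markers went both ways at CT16. Aldh1l1 fell by 0.35 ± 0.06, while Gja1 (0.32 ± 0.07) and Agt (0.40 ± 0.10) rose; 11 of the 14 did not pass, and adjusted over the list alone 6 rose and 1 fell. Of 22 genes of fatty acid and lipid handling, Fabp7 rose, the desaturase genes Fads2 (-0.44 ± 0.05) and Fads1 (-0.42 ± 0.07) fell and 19 did not pass; adjusted over the list alone 2 rose and 2 fell. Neither list passed its test, and the median of the lipid list (-0.03) lay below 0 while its test gave the higher direction. The potassium channel gene Kcna2 rose by 0.44 ± 0.07, the GABA receptor subunit gene Gabre fell by 0.45 ± 0.11, and the complement gene C4b rose by 1.86 ± 0.37. Of 16 SCN identity factors and markers, Rgs16 (2.39 ± 0.34) and Rasl11b (2.17 ± 0.40) rose and 14 did not pass, with 2 rising adjusted over the list alone, and the list did not pass (camera, adjusted p = 0.152).

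At CT16 the following lists of tissue markers, of signalling and receptor genes and of immediate early genes moved with genotype. None of them had a member called over all genes or adjusted over the list alone. Neighbouring hypothalamic nuclei were lower in DKO (median -0.40, camera, adjusted p = 0.0436, adjusted p = 0.647 with an estimated correlation), as were feeding and energy-balance signalling genes (median -0.39, camera, adjusted p = 0.0472, adjusted p = 0.647 with an estimated correlation) and immediate early genes (median -0.24, camera, adjusted p = 0.0472, adjusted p = 0.647 with an estimated correlation). Oligodendrocyte and myelin markers were higher (median 0.73, camera, adjusted p = 0.0159, adjusted p = 0.647 with an estimated correlation), and so were microglia markers (median 0.23, camera, adjusted p = 0.0335, adjusted p = 0.647 with an estimated correlation). Receptors of SCN neuropeptides and light input were lower (median -0.14, camera, adjusted p = 0.0472, adjusted p = 0.265 with an estimated correlation). DKO CT16 replicate 4 had a myelin score of 1.585 and DKO CT16 replicate 3 a neighbouring nuclei score of 0.657, against -0.987 to -0.637 in the other DKO CT16 libraries. Control CT16 replicate 5 had a neighbouring nuclei score of 0.609 and a feeding and energy-balance score of 0.789, against -0.508 to 0.133 and -0.583 to 0.12 in the other control CT16 libraries, and none of these 6 lists passed without it (adjusted p = 0.0517 to 0.225). With RLE factors the 4 lower ones did not pass (adjusted p = 0.0507 to 0.053). Without these DKO libraries and control CT4 replicate 1, 419 genes were called at CT16, 348 of them among the 788. Leaving out single libraries gave 380 to 1318 called genes, the lowest without DKO CT16 replicate 2 and the highest without DKO CT16 replicate 1.

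Genotype effects at the separate times shared genes although they share no library. Of the 217 and 788 called genes, 77 were called at both times: 60 were higher in DKO at both, 15 were lower at both and 2 changed in opposite directions. Independent lists of these sizes would share 2.74 higher and 2.2 lower genes. Both lists rest on 1 estimate of spread per gene from the same fit, so they are not independent and this baseline may be too low. Across the 788 genes called at CT16, the fold changes at CT4 and CT16 correlated at r = 0.771, and across all 16910 genes at r = 0.164; these are correlations across genes, which are not independent replicates.

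**Figure D2:**
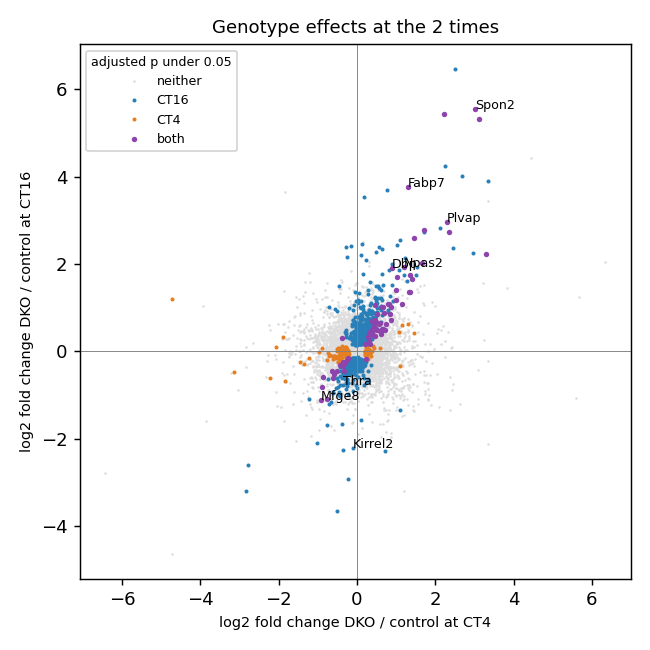
Log2 fold change of DKO over control at CT4 (x axis) and at CT16 (y axis) for 16910 genes, coloured by whether the gene passed an adjusted p of 0.05 at neither time, at CT4, at CT16 or at both. Spon2 lies at 3.02 and 5.55, and Mfge8 at -0.92 and -1.12.

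The comparison of CT16 with CT4 in control set the times against each other in mice with both receptors. Glucocorticoid-responsive genes rose together: Sgk1 by 2.80 ± 0.51, Plin4 by 2.58 ± 0.27, Tsc22d3 by 1.75 ± 0.08 (adjusted p = 2.39e-09), Zbtb16 by 2.04 ± 0.31 and Cdkn1a by 1.72 ± 0.15. The immediate early gene Fosb rose by 3.37 ± 0.38, Hif3a by 2.93 ± 0.17 and Arl4d by 2.92 ± 0.38. Fabp7 fell by 2.07 ± 0.16, the SCN genes Rasl11b and Rgs16 by 1.81 ± 0.42 and 1.72 ± 0.36, and the matrix metalloproteinase gene Mmp14 by 1.44 ± 0.14. Nr1d1 fell by 0.75 ± 0.13 (adjusted p = 0.00589), while Nr1d2 stood at -0.15 ± 0.08 (adjusted p = 0.302).

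In control, 712 genes passed, 360 higher and 352 lower at CT16; 60 rose and 47 fell by more than 2-fold. No overlap was seen in 15.8% of genes, where chance gives 3.57%. Lhx6 (3.85 ± 0.96), Hmx2 (2.87 ± 0.66) and Hmx3 (2.61 ± 0.66), transcription factor genes of forebrain and hypothalamic neurons, were also among the 8 largest rises, and Fzd10, Ctxn3, Tmem51 and Prdm13 among the 8 largest falls, at -1.65 to -1.34. Of the 17 glucocorticoid-responsive genes, 12 rose and 5 did not pass (16 rose adjusted over the list alone, camera, adjusted p = 7.49e-55, adjusted p = 0.00064 with an estimated correlation). Of the 19 temperature-responsive genes, 9 rose and 10 did not pass (13 rose adjusted over the list alone, camera, adjusted p = 3.98e-14, adjusted p = 0.0672 with an estimated correlation), with Hspa1b at 1.25 ± 0.21, Rbm3 at 0.64 ± 0.08 and Dnajb1 at 0.60 ± 0.10. Of 21 immediate early genes, 5 rose, Ier5 fell (-0.66 ± 0.14) and 15 did not pass (6 rose and 2 fell adjusted over the list alone, camera, adjusted p = 0.000429, adjusted p = 0.856 with an estimated correlation); Egr3 rose by 1.66 ± 0.30 and Jun by 0.38 ± 0.08.

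The clock lists did not move as sets with time in control. Usp2 rose by 0.92 ± 0.10, and Dbp and Bhlhe40 fell by 0.81 ± 0.16 and 0.41 ± 0.09, while 9 of the 12 repressors and outputs did not pass; adjusted over the list alone 3 rose and 4 fell (camera, adjusted p = 0.89). Per2 stood at 0.70 ± 0.21 (adjusted p = 0.0831). Nfil3 rose by 0.59 ± 0.15, 1 of 9 genes with ROR/REV-ERB elements, also 1 adjusted over the list alone (median -0.05 but higher direction by camera, adjusted p = 0.958); Arntl stood at -0.16 ± 0.14.

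Markers of microglia and astrocytes were lower at CT16 in control. Of 14 microglia markers, 4 fell and 10 did not pass (7 fell adjusted over the list alone, camera, adjusted p = 2.75e-06, adjusted p = 0.856 with an estimated correlation), among them Cx3cr1 (-0.68 ± 0.13) and P2ry12 (-0.57 ± 0.13). Of 14 astrocyte markers, Sox9 (-0.54 ± 0.09), Slc7a10 (-0.39 ± 0.07) and S1pr1 (-0.22 ± 0.06) fell and 11 did not pass (6 fell and 1 rose adjusted over the list alone, camera, adjusted p = 0.00181, adjusted p = 0.856 with an estimated correlation). Of 16 markers of endothelium and mural cells, 2 rose, 3 fell and 11 did not pass (2 rose and 6 fell adjusted over the list alone, camera, adjusted p = 0.0678): the glucose transporter gene Slc2a1 rose by 0.71 ± 0.06, while the tight junction gene Cldn5 (-1.04 ± 0.12) and the receptor genes Kdr (-0.92 ± 0.15) and Pdgfrb (-0.53 ± 0.10) fell. SCN identity factors and markers were lower, with Rgs16, Rasl11b and Six6 (-0.99 ± 0.25) called and 13 not (4 fell and 1 rose adjusted over the list alone, camera, adjusted p = 0.0301, adjusted p = 0.915 with an estimated correlation). Myelin markers were lower without a called member, also adjusted over the list alone (median -0.52, camera, adjusted p = 0.0394, adjusted p = 0.915 with an estimated correlation). Control CT16 replicates 3 to 5 had myelin scores of -1.039 to -0.78, while replicates 1 and 2 (0.204 and 0.489) lay near the control CT4 libraries (-0.075 to 0.443), and without any of replicates 3 to 5 neither the myelin nor the SCN identity list passed (adjusted p = 0.0519 to 0.21). Ribosomal protein genes were higher (median 0.09, 1 of 28 called, Rps24, and 1 adjusted over the list alone, camera, adjusted p = 0.00075, adjusted p = 0.856 with an estimated correlation). Of 23 markers of neighbouring nuclei, Crh rose (4.31 ± 1.11), Foxb1 fell (-0.87 ± 0.15) and 21 did not pass (2 rose and 1 fell adjusted over the list alone, camera, adjusted p = 0.24). Of 12 markers of striatum and basal forebrain, Lhx8 rose (4.08 ± 0.94) and 11 did not pass (2 rose adjusted over the list alone, median -0.03 but higher direction by camera, adjusted p = 0.602). Crh and Lhx8 were near the floor in control at CT4, with means of 0.19 and 0.13 CPM. At CT16 they were uneven, at 3.7 ± 1.9 and 2.1 ± 1.2 CPM (SD, n = 5). Of 21 alternatives, the call of Hmx3 was lost in 14, those of Lhx6 and Crh in 13, S1pr1 in 12, Rps24 in 11, Hmx2 and Six6 in 10 and Lhx8 in 9. Leaving out single libraries gave 235 to 857 called genes; 235 were called without control CT4 replicate 2.

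In DKO, the same comparison between times again showed the glucocorticoid-responsive genes rising: Arl4d by 3.05 ± 0.38, Sgk1 by 2.97 ± 0.52, Plin4 by 2.41 ± 0.27, Cdkn1a by 1.97 ± 0.15 and Zbtb16 by 1.84 ± 0.32. Fosb rose by 2.04 ± 0.37. Hes5, a Notch target, fell by 1.29 ± 0.19, Lgr6 by 1.21 ± 0.27 and the microglial receptor gene P2ry13 by 0.96 ± 0.13. Clock genes Per1 (0.72 ± 0.12), Usp2 (0.85 ± 0.10), Npas2 (0.71 ± 0.16) and Nfil3 (0.61 ± 0.15) rose, as did Nr1d2 (0.45 ± 0.08), while Nr1d1 stood at 0.41 ± 0.14 (adjusted p = 0.136). The calls of Npas2 and Nfil3 were each lost in 11 of 20 alternatives.

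In DKO, 304 genes passed between the times, 218 higher and 86 lower at CT16; 31 rose and 10 fell by more than 2-fold. No overlap was seen in 14.7% of genes, where chance gives 5.71%. Fam83d (2.17 ± 0.51) and Plekhf1 (1.84 ± 0.39) were among the largest rises, and Tap1, Socs3, Foxb1, Spint1 and Kcnk12 among the largest falls, at -0.96 to -0.92; the call of Tap1 was lost in 10 of 20 alternatives. Of the 17 glucocorticoid-responsive genes, 14 rose and 3 did not pass (17 rose adjusted over the list alone, camera, adjusted p = 2.22e-67, adjusted p = 0.000273 with an estimated correlation). Of the 12 clock repressors and outputs, Per1 and Usp2 rose and 10 did not pass (6 rose and 1 fell adjusted over the list alone, camera, adjusted p = 3.86e-06, adjusted p = 0.385 with an estimated correlation), and of the 9 genes with ROR/REV-ERB elements Npas2 and Nfil3 rose and 7 did not pass (6 rose adjusted over the list alone, camera, adjusted p = 0.0015, adjusted p = 0.385 with an estimated correlation). Of the 21 immediate early genes, Fosb, Fosl2 (1.68 ± 0.28) and Nr4a3 (1.48 ± 0.28) rose and 18 did not pass (5 rose and 1 fell adjusted over the list alone, camera, adjusted p = 0.00538, adjusted p = 0.653 with an estimated correlation). Of the 19 temperature-responsive genes, Chordc1 rose by 0.47 ± 0.08 and 18 did not pass (3 rose adjusted over the list alone, camera, adjusted p = 0.00339, adjusted p = 0.653 with an estimated correlation).

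Microglia markers were lower at CT16 in DKO as well (median -0.22): Cx3cr1 fell by 0.66 ± 0.14 and P2ry12 by 0.62 ± 0.14, and 12 of 14 did not pass (2 fell adjusted over the list alone, camera, adjusted p = 0.00188, adjusted p = 0.653 with an estimated correlation). Of 16 markers of endothelium and mural cells, Cldn5 fell by 0.83 ± 0.13, Kdr fell by 0.77 ± 0.16, Slc2a1 rose by 0.77 ± 0.07 and 13 did not pass (2 rose and 4 fell adjusted over the list alone, camera, adjusted p = 0.446). Of 14 astrocyte markers, the gap junction gene Gjb6 rose by 0.52 ± 0.07, Sox9 (-0.39 ± 0.09) and Slc7a10 (-0.30 ± 0.07) fell and 11 did not pass (1 rose and 2 fell adjusted over the list alone, camera, adjusted p = 0.734). Markers of neighbouring nuclei were lower at CT16 (median -0.64, Foxb1 called and 22 not; adjusted over the list alone 2 fell, camera, adjusted p = 0.000351, adjusted p = 0.565 with an estimated correlation), and SCN identity markers were higher with none called (median 0.60; adjusted over the list alone 4 rose and 1 fell, camera, adjusted p = 0.00423, adjusted p = 0.653 with an estimated correlation). Feeding and energy-balance genes were lower (median -0.40, Socs3 called; adjusted over the list alone 1 rose and 1 fell, camera, adjusted p = 0.0444, adjusted p = 0.719 with an estimated correlation). Nuclear RNAs were higher (median 0.11, none called; adjusted over the list alone 2 rose, camera, adjusted p = 0.0386, adjusted p = 0.653 with an estimated correlation). Ribosomal protein genes were lower, none called, also adjusted over the list alone (median -0.08, camera, adjusted p = 0.0126, adjusted p = 0.679 with an estimated correlation). The microglia, feeding and energy-balance, nuclear RNA, ribosomal protein and temperature-responsive lists did not pass without DKO CT16 replicate 1 (camera, adjusted p = 0.0542 to 0.101). Microglia and ribosomal protein lists did not pass without DKO CT16 replicate 3 either (camera, adjusted p = 0.064 and 0.0877). Without DKO CT16 replicate 3, 1461 genes were called, and without DKO CT4 replicate 2, 103. With the 3 libraries that stand apart in tissue markers left out, 1184 genes were called, 285 of them among the 304.

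**Figure D3:**
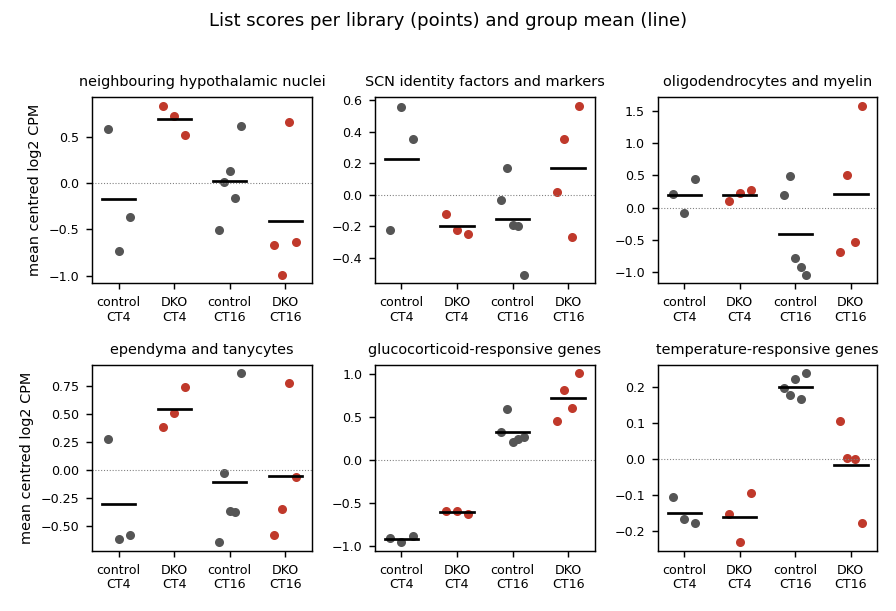
Score of 6 gene lists in each library (points; black lines are group means), as the mean over list members of log2 CPM centred on the 15-library mean, by genotype and circadian time. Glucocorticoid-responsive genes have group means of -0.91 and -0.60 at CT4 and 0.33 and 0.72 at CT16 (control and DKO), and neighbouring nuclei scores spread from -0.987 to 0.657 within the DKO CT16 group.

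The time effects of both genotypes shared 118 called genes by the same test. Of these, 87 were higher and 31 lower at CT16 in both, and 0 went in opposite directions. Independent lists of these sizes would share 4.64 and 1.79. These lists too use 1 estimate of spread per gene from the same fit, so this baseline may be too low. Fold changes correlated across the 304 genes called in DKO at r = 0.832 and across all 16910 genes at r = 0.208.

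The interaction tested whether the genotype effect differed between the times. Fabp7 had a genotype effect larger at CT16 by 2.46 ± 0.24 (adjusted p = 0.00192), with 1.30 ± 0.18 at CT4 and 3.76 ± 0.16 at CT16, and Pla2g3, a secreted phospholipase gene, by 1.79 ± 0.27 (adjusted p = 0.0382). These were the 2 genes that passed, with 2557 at an unadjusted p under 0.05. The next smallest p-values were those of Atpif1, Hif3a (-1.43 ± 0.23), Nsun7 (all adjusted p = 0.0511), Aoc1 (3.23 ± 0.54), Nr1d1 (1.16 ± 0.19), Mmp14, Igf1r and Pde2a (all adjusted p = 0.0517). Among clock genes, Dbp stood at 1.01 ± 0.23 (adjusted p = 0.113), Ciart at 0.95 ± 0.21 (adjusted p = 0.102), Npas2 at 0.73 ± 0.22 (adjusted p = 0.168) and Nfil3 at 0.02 ± 0.20, none of which passed. The call of Fabp7 held in all 27 alternatives, while that of Pla2g3 was lost in 10, and 1 gene was left when any of 8 single libraries was left out. Other tools called more genes in this contrast, 368 with DESeq2 and 420 with limma voom, and 298 were called without DKO CT16 replicate 3.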

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

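Chosen only after the result was seen were the tests on DKO CT16 replicate 3, those of mixing and of a swap on control CT4 replicate 1, the test of shared reads at Thra, the list tests of the interaction and the counts over other splits of the libraries. The tests of tissue makeup and of linked variants had bounds set before their results were seen, but that of tissue makeup was given a further requirement afterwards.

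In 18 of 228 groups tested, 1 library lay far from the others of its group, where chance gives about 1 in 20 groups. Only groups with at least 4 libraries were tested. The CT4 groups, with 3 libraries each, were not screened, so no CT4 library could appear here. DKO CT16 replicate 3 had 44.96 CPM of Npas2 (72.44 to 74.66 in the others), 22.89 of Nfil3 (38.13 to 39.06), 67.81 of Mfge8 (54.34 to 55.39), 5.891 of Prdm13 (2.008 to 2.592) and an endothelium and mural cell score of 0.081 (-0.166 to -0.139). DKO CT16 replicate 4 had 342.2 CPM of Tef (396.8 to 400.9) and a fibroblast and meninges score of 0.558 (-0.143 to -0.026). DKO CT16 replicate 1 had 6.896 CPM of Lhx6 (0.7493 to 1.531), and DKO CT16 replicate 2 had 105.9 CPM of Igf1r (100.7 to 100.9). Control CT16 replicate 2 had 5.676 CPM of Aldh1a2 (1.952 to 3.01), 33.25 of Col9a3 (27.73 to 28.83) and an astrocyte score of 0.138 (-0.187 to -0.111). Control CT16 replicate 3 had a nuclear RNA score of -0.486 (-0.082 to 0.066) and a sex-linked gene score of -0.596 (-0.074 to 0.104). Control CT16 replicate 5 had 4.435 CPM of Crispld2 (2.855 to 2.948) and 6.718 of Lgr6 (3.343 to 4.005), control CT16 replicate 4 had 17.32 of Elovl2 (10.87 to 12.14), and control CT16 replicate 1 had 43.13 of Nr4a3 (21.78 to 27.11).

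The genotype effect differed between the times by the interaction test for Fabp7 (2.462 higher at CT16 on the log2 scale) and Pla2g3 (1.793). By camera on the interaction, the effect at CT16 minus that at CT4 differed for 8 lists, given here as medians. They were clock repressors and E-box outputs (0.1717, adjusted p = 4.98e-05), clock genes with ROR/REV-ERB elements (0.2965, adjusted p = 0.0121), SCN identity factors (0.8906, adjusted p = 1.14e-05), feeding and energy balance (-0.6013, adjusted p = 0.00158), neighbouring nuclei (-0.7376, adjusted p = 1.14e-05), temperature-responsive genes (-0.129, adjusted p = 0.000922), nuclear RNAs (0.2514, adjusted p = 0.0157) and ribosomal proteins (-0.1399, adjusted p = 9.98e-07). With an estimated correlation none of the 8 passed, at adjusted p = 0.499 to 0.51.

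DKO CT16 replicate 3 stands apart from the other DKO CT16 libraries, with lower Npas2 and Nfil3. A CT4 library carrying a CT16 label is argued against by 12 glucocorticoid-responsive genes, whose median position was 0.893 (quartiles 0.797 to 1.05) from the DKO CT4 mean at 0 to the other DKO CT16 libraries at 1. More tissue from outside the SCN remains a candidate explanation, since the neighbouring nuclei score was 0.657 against -0.987 to -0.637. A difference between animals was not tested.

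Control CT4 replicate 1 lies towards the DKO libraries, with 1.37 CPM of Spon2 against 0.288 and 0.29 in the other control CT4 libraries. Over 60 of the 91 genes more than 2-fold higher in DKO at CT16, those with a log2 change over 0.5 at CT4, its median position from control (0) to DKO (1) was 0.18, against -0.0842 and -0.121. Each library was placed against the mean of the other control CT4 libraries. A high library therefore lowers the positions of the others by construction, and they are no independent reference. The upper quartile of 0.292 for replicate 1 argues against a swap, while a share of DKO tissue or RNA is not excluded. With tissue scores in the model the median excess of replicate 1 was 0.261, above the -0.275 to 0.24 of the 7 other control libraries. By the bound set beforehand this outcome goes against tissue makeup. The excess lies above the others by less than their spread, a requirement added afterwards, so tissue makeup is left as a cause that cannot be told apart. Some strongly changed genes showed no such shift, with positions of 0.0122 for Npas2, 0.00295 for Cdkn1a, -0.000743 for Arntl and -0.0707 for Dbp.

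Thra, which lies next to Nr1d1 on chromosome 11 (98741873 to 98765111, plus strand), fell by 0.77 ± 0.08 in DKO at CT16 while Nr1d1 counts rose. In the annotation used, 0% of the 2246 exonic bases of Thra overlap exons of Nr1d1, while Thra lost 41.3%. Reads shared between annotated exons thus cannot make the fall. This follows from the gene coordinates alone and draws on no reads. Transcripts that reach past the annotated ends were not tested, and the strand setting is not given, so shared reads are not excluded. Variants linked to the deleted genes cannot be told apart from an effect of the receptors. Within 5 Mb of Nr1d1 or Nr1d2, 22 of 302 genes were called (7.28% against 4.6% elsewhere). The odds ratio over both windows was 1.63 (95% interval 0.999 to 2.53, Fisher's exact test, 2-sided p = 0.0371). Of the 22 called genes, only Adk lies on chromosome 14, near Nr1d2. The others lie on chromosome 11 and include Thra, which was chosen after its value was seen. The window of Nr1d1 was not tested alone, so these values do not measure calls at that locus. An effect of the deletion itself on transcription at the locus was not tested.

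The libraries were also split into other groups of the same sizes. At CT16, 3 of 100 splits, the real one included, called as many genes as the real 788, a share under 0.05. The highest other split called 1422 genes, more than the real one, so this count alone cannot tell genotype from other structure of the samples. That split exchanged DKO replicate 1 with control replicate 2, which points to a structure of the samples, whose source was not tested. For time in control it was 1 of 56 splits (712 real, highest other 2), also a share under 0.05. With only 3 control CT4 libraries this makes chance unlikely but does not exclude it. Nor does this count tell time from other differences between the groups. For time in DKO, 2 of 35 splits called as many (304 real, highest other 1396), and for the interaction 5 of 100 (2 real, highest other 413), so chance was not excluded; the split with 1396 sets DKO CT16 replicate 3 with the DKO CT4 libraries, which also points to a structure of untested source. At CT4 the 10 splits are too few for a share under 0.05 (217 genes real, highest other 0; 10 lists real, highest other 8; 1 split each as large). For the lists, 44 of 100 splits at CT16 (10 real, highest other 16), 23 of 56 for time in control (8 real, highest other 15) and 13 of 35 for time in DKO (11 real, highest other 15) called as many, so chance was not excluded for these counts.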

How the results depend on the processing

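Covariates for tissue other than myelin alone, sva and the exclusion of 3 libraries are tests chosen after the data were seen. No named gene changed direction where it was called in either fit. Of 8646 values of named genes under alternatives, 7583 stayed on their side of the threshold, 622 were weaker and 441 stronger. The alternatives include removal of mitochondrial and haemoglobin genes, which took away no tested gene and could not change a call. Calls of named genes held under every alternative for 7 of 31 at CT4, 36 of 53 at CT16, 23 of 51 for time in control, 8 of 40 for time in DKO and 1 of 2 (Fabp7) for the interaction. Where counts moved by more than 1.5 times, the cause was not tested. The 217 genes at CT4 became 650 with a myelin covariate, 606 without 3 libraries, 828 with the compared groups alone, 591 with DESeq2 and 822 with voom. The 788 at CT16 became 419 without 3 libraries, 368 with the compared groups alone and 1284 with DESeq2. The 712 for time in control became 1196 with myelin and neighbouring nuclei covariates, 1318 with DESeq2 and 1816 with voom. The 304 for time in DKO became 1141 with a myelin covariate, 194 with both covariates, 187 with sva, 1184 without 3 libraries, 47 with the compared groups alone, 879 with DESeq2 and 1310 with voom. The 2 interaction genes became 6 with no filter, 83 with a myelin covariate, 15 with both covariates, 8 with sva, 423 without 3 libraries, 368 with DESeq2 and 420 with voom. The balance at CT4, 97 higher and 120 lower, turned with sva (122 and 95), both covariates (103 and 73), the replicate block (28 and 17) and without DKO replicates 1, 2 or 3 (27 and 13, 17 and 8, 22 and 9) or control replicates 2 or 3 (15 and 4, 11 and 5). For time in control, 360 higher and 352 lower turned with upper quartile factors (299 and 423), voom (897 and 919), the replicate block (214 and 222) and without 3 libraries (283 and 326). With an estimated correlation, 0 of 10 lists at CT4, 2 of 10 at CT16, 1 of 8 for time in control and 1 of 11 for time in DKO passed. At CT16, where 5 lists were higher and 5 lower, 6 passed with RLE factors (5 higher and 1 lower) and 6 with a myelin covariate (3 and 3), and for time in DKO 5 with both covariates.

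With the number as a replicate block, 45 genes were called at CT4, 351 at CT16, 436 for time in control, 242 for time in DKO and 3 for the interaction, and 13, 8, 6 and 13 lists. Same-numbered libraries correlated in their deviations from group means at -0.0647 to -0.0218 between genotypes at CT4, -0.184 to 0.138 at CT16, -0.144 to 0.0305 between times in control and 0.0503 to 0.1 in DKO, where each of 3 matched its own number best.

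Leaving out 1 library gave 16 to 190 genes at CT4 (40, 25 and 31 without DKO replicates 1, 2 and 3; 19 and 16 without control replicates 2 and 3; 190 without control replicate 1). At CT16 it gave 380 to 1318 (1318, 380 and 490 without DKO replicates 1, 2 and 4; 513 without control replicate 4). For time in control it gave 235 to 857 (267, 235 and 332 without control CT4 replicates 1, 2 and 3; 410, 447 and 471 without control CT16 replicates 3, 4 and 5). For time in DKO it gave 103 to 1461 (161, 103 and 108 without DKO CT4 replicates 1, 2 and 3; 191, 141 and 1461 without DKO CT16 replicates 1, 2 and 3). For the interaction it gave 1 to 298 (298 without DKO CT16 replicate 3, 12 without control CT16 replicate 2, 4 without control CT4 replicate 1; 1 without DKO CT4 replicates 1 or 2, control CT4 replicates 2 or 3, DKO CT16 replicate 4, or control CT16 replicates 3, 4 or 5). Lists numbered 9 to 13 at CT4, 5 to 14 at CT16 (6 without DKO replicates 2 or 4, 5 without control replicate 5, 4 higher and 1 lower), 6 to 9 for time in control and 6 to 12 for time in DKO (6 without DKO CT16 replicate 1).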

Other observations

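The test of the slope had its bounds set before its result was seen, while the genes beside Thra were looked at only after their values were known, with no tests of their own.

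Of 31 lists tested, 15 passed in none of the 4 comparisons, the lowest adjusted p being 0.0507 (camera). They were SCN neuropeptides, ion channels, GABA signalling, glutamatergic neurons, striatum and basal forebrain, thalamus, oligodendrocyte precursors, endothelium, fibroblasts, choroid plexus, pituitary, cholesterol synthesis, lipid handling, haem and redox, and sex-linked genes. Single members of these lists, and of lists that passed in other comparisons, were called. In DKO at CT16, Ppp1r1b, a striatal phosphatase inhibitor, rose by 1.52 ± 0.22, the folate receptor gene Folr1 by 1.34 ± 0.36 and the ependymal Tmem212 by 0.56 ± 0.14, while Rgs9 fell by 0.23 ± 0.06. The calls of Folr1 and Rgs9 were each lost in 10 of 22 alternatives, that of Tmem212 in 7 and that of Ppp1r1b in 1. Folr1 was low, with a mean of 0.45 CPM in control and 1.14 CPM in DKO at CT16. Between times in control, the neurotrophin gene Bdnf rose by 1.11 ± 0.24, the lipase gene Pnpla2 by 0.43 ± 0.07, Kcnk1 by 0.34 ± 0.07 and Prkcd by 0.40 ± 0.10. Of 21 alternatives, the call of Prkcd was lost in 8, that of Bdnf in 3 and that of Kcnk1 in 1. Between times in DKO, the collagen gene Col1a2 rose by 0.50 ± 0.10, the calcium channel gene Cacna1c by 0.26 ± 0.06 (lost in 10 of 20 alternatives) and Lpin1 by 0.24 ± 0.05, while H2-D1 fell by 0.46 ± 0.09. The calls of Col1a2 and Lpin1 were each lost in 7 of the 20 alternatives and that of H2-D1 in 4. The blood list had 4 tested genes, too few for the test, and 0 were called. Pituitary scores were highest in control CT4 replicate 2 (2.682) and control CT16 replicate 2 (2.156).

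On chromosome 11 within 5 Mb of Nr1d1, 6 genes rose in DKO at CT16, Ppp1r1b as given above, Tcap by 2.83 ± 0.65, 1700003D09Rik by 1.76 ± 0.32, E130012A19Rik by 1.09 ± 0.19, Gpr179 by 0.78 ± 0.18 and Rsad1 by 0.51 ± 0.06. Med24 fell by 0.25 ± 0.05, Msl1 by 0.20 ± 0.05, Casc3 by 0.20 ± 0.05 and Psmd3 by 0.18 ± 0.05, and besides Thra 10 other genes fell, by 0.15 to 0.41.

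Fold changes of all genes at CT4 correlated across genes with exonic length at Spearman -0.13 and with GC content at 0.0339, and at CT16 at 0.0284 and -0.162. For time in control these were -0.0667 and 0.0314, for time in DKO 0.0936 and -0.141, and for the interaction 0.117 and -0.132.

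A hypothesis was that the DKO SCN at CT16 lies nearer to CT4 than control does. Over 500 genes with the largest time statistic, with separate control CT16 libraries for each difference, the slope of the genotype difference on the time difference had a median of -0.26 (range -0.326 to -0.101 over 10 splits). The bound of -0.2 was not met in every split, so the hypothesis stays open.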
